A study of Mus musculus with 2 samples.

How the data were processed

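The measurement was ChIP-seq of H3K27ac in mouse forebrain at embryonic day 16.5, in 2 biological replicates of 1 group. Per the labels, both replicates were tissue pooled from male and female embryos of the same strain, replicate 2 came from 41 embryos, the library size range was 300 to 500, and the assembly was mm10. The replicate numbers were taken from the labels. The deposited files used were 4 peak lists without header lines, in the layout of narrowPeak, and a short text listing beside them that says which files each list was derived from. Per that deposited listing, each replicate had its own list, the pooled list was made from the alignments of both replicates, and the replicated list was derived from the pooled list and the lists of both replicates. The list of replicate 1 and the pooled list also drew on 1 further file of unstated role that the list of replicate 2 did not. The aligner, the peak caller, its thresholds and the rule for calling a peak replicated are not given in the sources used here. Every peak of the replicated list had the same start and end as a peak of the pooled list.

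The signal value of each peak was set by the authors' peak caller before deposition, and its scale is not named in the deposited files. It was used only to describe, rank or filter peaks within a list, and ratios between the replicates' lists carry that limit. The deposited −log10 p-value and −log10 q-value of each peak were likewise given by the authors' caller and were used only as stricter thresholds. Peak starts, ends and summits were read as deposited, and positions are printed counting from 1. Read depth is unknown for both replicates, since the lists hold no read counts, so no statement rests on depth and no interval for a signal value could be made. The 95% Wilson intervals of shares treat peaks or genes as independent and cover counting error only.

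The reference was GRCm38, the assembly that mm10 names, with the GENCODE vM21 annotation. The chromosome lengths of the reference hold every deposited peak on the autosomes, X and Y. Peaks on the autosomes, X and Y were used. The peaks on other scaffolds, 10 of the replicated list, were left out of the report. All 21853 protein-coding genes on these chromosomes were used with all their annotated transcript starts. A promoter peak touched the 1 kb on either side of a start, and every other peak was distal. Distal peaks went to the nearest protein-coding start within 500 kb.

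Choices were fixed before the data were examined: 27 gene lists of 8 to 39 members, 23 motif words, the tests, the thresholds and most alternatives. Of 391 list members 390 were found in the annotation, and Ahsp was not. Peaks of the replicates were called shared when they overlapped by at least 50% of the shorter peak, with chance from 100 circular shifts of 1 list along each chromosome (seed 7). The correlation of signal values was over overlapping pairs, each peak used once. Promoter peaks of gene lists were tested by Fisher's exact test, two-sided, against all other protein-coding genes. Distal peaks of gene lists were tested against 10000 random lists matched on the decile of the length of sequence nearest to the gene, with 2 times the smaller tail as p, so that the smallest p is 0.0002. Each random list was drawn without repeats within its deciles from all protein-coding genes, which amounts to a permutation of list membership within deciles, and the matching on promoter CpG did the same within quintiles. Distal peaks within 12.5 kb of each other were joined into stitched regions, ranked by the sum of signal value times width. For motifs, the 500 bp around each distal summit were searched on both strands and compared by Fisher's exact test with as many windows 3 to 10 kb away, outside the peaks of all lists and matched on GC content in bins of 2 percentage points. Each family was adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05.

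Genes were named by a rule fixed before the data were examined. It takes the 20 genes with the highest promoter signal value, the nearest protein-coding gene of the top 20 stitched regions, and up to 6 members of each list that stand against it, those without a promoter peak in forebrain and general lists and those with one in lists of other cells and tissues. It also takes the 3 members of each list with most distal peaks, and the 10 genes of each replicate with the highest promoter peak and none in the other replicate's list. Further members of the lists are named as examples of their group, and those on chromosome X because of their position. The gene families, microRNA lists, widest peaks and genes with most distal peaks in the closing section were chosen after the data were seen.

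The alternatives fixed beforehand were an overlap of 1 bp or of 50% of both peaks, −log10 q-values of at least 2 or 5, equal numbers of top peaks (50% of the shorter list), the top 50% of peaks by signal value, the pooled list, the list of each replicate alone, promoter windows of 500 bp or 2.5 kb, the most upstream start only, random lists matched on the quintile of promoter CpG count, a distance limit of 100 kb, every start within 50 kb, stitching at 5 or 25 kb, motif windows of 200 bp, and control windows matched on GC and CpG. Added after the data were seen were the replicated peaks found in both replicates' lists, the starts of all annotated genes, and a motif search without repeats.

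The replicate overlap, both tests of gene lists and the motif test were tried on simulated data with known answers. Other statistics, such as the signal correlation, the stitched regions and the X ratio, were not. For the overlap of 69558 peaks, 59.9% were planted as shared and 59.9% were recovered. Promoter lists were planted with 95% of members flagged among 21853 genes flagged at 50%. Of 900 such lists 806 (89.6%) were recovered, with 25 false calls among 1800 unplanted lists. Genes were flagged independently of CpG content and position. No list with fewer peaks was planted, so the recovery of such lists was not tried. For distal lists with 3 times the peaks of matched genes, 21 of 54 (38.9%) were recovered, with 1 false call of 108, so many changes of that size would be missed. For motifs in 19998 windows of random sequence, 2 of 2 planted words were recovered, with an estimated gain of 2.86 percentage points for 3 planted. Of the other words 0 of 21 were called, but random sequence does not show how often genomic windows give false calls. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.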

Results

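Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos at day 16.5, a stage at which cortical neurons are being produced. The series held 1 group with 2 biological replicates, each of them tissue pooled from embryos of both sexes. The label of replicate 2 named 41 embryos, and that of replicate 1 gave no number. The measurements were 4 lists of peaks on the mm10 genome: the list of each replicate, a list called on both replicates together, and a replicated list that was a subset of the pooled one. The replicated list held 50762 peaks with a median width of 432 bp, and it covered 33.7 Mb or 1.23% of the genome. The pooled list held 58350 peaks, the list of replicate 1 held 69569 and that of replicate 2 held 42342. The sequencing depth of both replicates is unknown, because the lists carry no read counts. The design names no second tissue, age or treatment, so the comparisons were between the replicates, between groups of genes, and between places in the genome. Values given for the group are those of the replicated list unless a replicate is named, and they have no replicate error of their own.

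The first question was how far the replicates carried the same peaks. The highest peak of all 4 lists stood at the promoter of Klf7, a transcription factor of neuronal outgrowth, with a signal value of 67.8 in replicate 1 and 57.4 in replicate 2. Foxg1, the factor that sets forebrain identity, had a promoter peak of 42.8 in replicate 1 and 29.3 in replicate 2. Neurod2, a factor of cortical excitatory neurons, had 31.0 and 22.3, and Actb, the gene for cytoplasmic beta actin, had 59.9 and 42.4. Of the protein-coding genes with a promoter peak, 9884 had one in both lists, 1436 in the list of replicate 1 only and 115 in that of replicate 2 only. The genes found in 1 list only had low peaks, with a median signal value of 3.99 against 11.2 for shared genes in replicate 1, and of 3.60 against 7.77 in replicate 2.

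Of the peaks of replicate 1, 33020 of 69558 on the assembled chromosomes (47.5%, 95% Wilson interval 47.1 to 47.8) overlapped a peak of replicate 2 by at least 50% of the shorter peak. In the other direction 36733 of 42334 did (86.8%, 86.4 to 87.1). Random shifts of a list along its chromosomes gave means of 1.17% and 1.90% and maxima of 1.36% and 2.21% over 100 shifts. Taller peaks were shared more often: 15.5% of the lowest decile of replicate 1 by signal value was shared and 99.9% of the highest, against 70.99% and 100% in replicate 2. Across 31799 overlapping pairs the signal values had a Spearman correlation of 0.762, which describes peaks and not independent samples. Asking for 50% of both peaks lowered the share for replicate 2 to 58.0%, and taking the 21167 highest peaks from each list, 50% of the length of replicate 2's, gave 75.1% for replicate 1 and 81.6% for replicate 2.

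**Figure D1:**
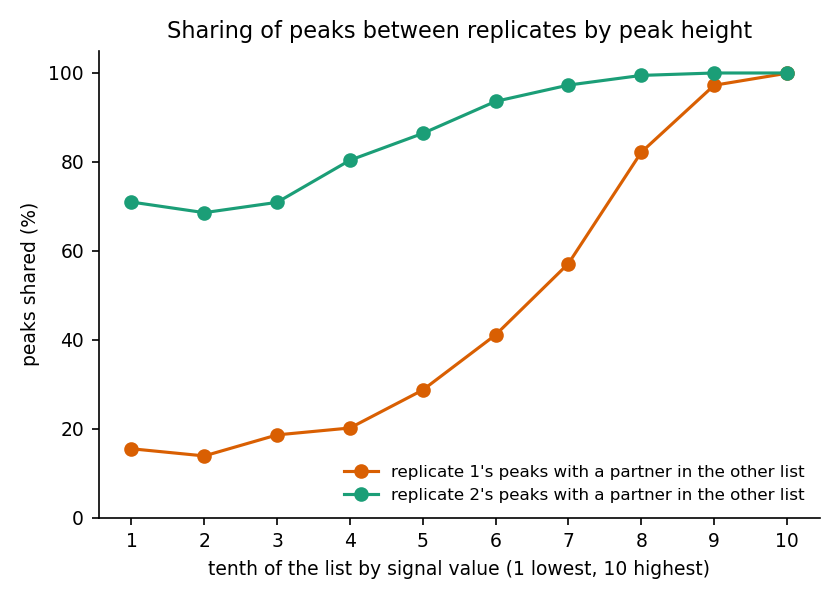
The share of peaks with a partner in the other replicate's list (vertical axis, percent) is plotted for each decile of a list by signal value (horizontal axis, 1 the lowest), in orange for replicate 1 and in green for replicate 2. The highest decile reaches 99.9% in replicate 1 and 100% in replicate 2, and the lowest lies at 15.5% and 70.99%.

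Among the 10 genes with the highest promoter peak in the list of replicate 1 and none in that of replicate 2, Slc35g3, the early response gene Fosb, Vpreb1, Ggt1 and Gm10647 had peaks of 26.5, 15.9, 15.1, 10.6 and 9.72 that overlapped a peak of replicate 2 lying outside the promoter window. The next 5 overlapped none: Clint1 at 8.86, Heatr5a at 8.73, Zfp445 at 8.55, Mthfsl at 8.25 and Vps39 at 8.25. The peak given for Slc35g3 was also the promoter peak of the housekeeping gene Polr2a, which had 26.5 in replicate 1 and 20.2 in replicate 2. For replicate 2 the 10 genes were Sh2d7 at 5.41, whose peak overlapped one of replicate 1, and Mybl1 at 5.40, Pigt at 5.21, Ldah at 5.08, Fam160a1 at 4.84, the synaptic vesicle gene Sv2b at 4.77, Tmtc1 at 4.42, Cyb5rl and Mrpl37, which share a peak, at 4.39, and Oas1c at 4.37.

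The second question was which pooled peaks the authors' replicated list kept. It kept 50752 of 58339 pooled peaks (87.0%, 95% Wilson interval 86.7 to 87.3). The kept peaks had a median signal value of 4.37 and a median width of 432 bp, and the others 2.95 and 208 bp. In the lowest decile by signal value 56.3% were kept, and 100% in the highest 2 deciles. Of the kept peaks, 32016 (63.1%) overlapped a peak in the lists of both replicates by the 50% rule, 14993 in replicate 1 only, 1762 in replicate 2 only and 1981 in neither. None of the 7587 other pooled peaks overlapped both.

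The third question was where the peaks lay relative to genes. Of the replicated peaks 14969 (29.5%, 95% Wilson interval 29.1 to 29.9) touched the 1 kb on either side of a protein-coding start. By protein-coding genes alone, 37.6% lay in introns, 30.5% between genes, 1.26% in untranslated regions and 1.15% in coding exons. Shifted peaks gave a promoter share of 3.21% on average and at most 3.55%. With the starts of all annotated genes, a setting chosen after the data were seen, the promoter share was 35.5% (18015 peaks). Promoter peaks were taller and wider than distal peaks, with a median signal value of 6.80 against 3.95 and a median width of 608 bp against 381 bp. The difference in median signal value was 2.59 in replicate 1 and 1.79 in replicate 2. The promoter share was 25.1% in replicate 1 and 33.9% in replicate 2, and the longer list had the lower share.

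Of 21853 protein-coding genes 10826 (49.5%, 48.9 to 50.2) had a promoter peak, against 51.8% in replicate 1 and 45.8% in replicate 2. The tallest stood at Klf7 (chr1:64117653-64123312, signal value 70.08) and at Sp3, a GC-box binding factor (chr2:72978465-72981336, 64.0). They were followed by Arrdc3 (chr13:80882503-80887147, 59.6), Epc1, a subunit of a histone acetyltransferase complex (59.4), Tnrc18 (chr5:142810679-142824869, 58.5), whose peak was 14191 bp wide, and Actb (58.3). The widest peak overlapping that of Tnrc18 had 13742 bp in replicate 1 and 6512 bp in replicate 2. The others of the top 20 were the pair Gm10762 and Zc3h6 at 55.6, the histone methyltransferase Kmt5b at 55.2, Pik3r3 at 54.0, the respiratory regulator Nrf1 at 53.9, the RNA-binding Pcbp1 at 53.8, Zfp143 at 53.4, Ing1 at 53.1, Mex3b at 52.8, Nfib at 51.5, Trim8 at 51.5, the pair Btf3l4 and Txndc12 at 50.6, and the histone demethylase Kdm3a at 49.9. Klf7 ranked 1 in the lists of both replicates, while Pik3r3 ranked 8 in replicate 1 and 63 in replicate 2.

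Gene lists fixed before the data were examined were then compared with all other protein-coding genes. Several lists of forebrain neurons and progenitors carried promoter peaks at nearly every member. All 18 pan-neuronal genes had one, among them Map2 (33.6), a dendritic microtubule protein, and Dcx (19.2), a protein of migrating neurons. So did all 13 radial glia genes, with Sox2 at 24.5 and Notch1 at 19.3, and all 12 telencephalic patterning factors, with Nr2f1 at 43.6 and Foxg1 at 39.1. Of 19 cortical projection neuron genes 18 had a peak, with Bcl11b, a factor of subcerebral neurons, at 39.1 and Tbr1, a factor of deep-layer neurons, at 26.4. Of 15 synaptic receptors and transporters 14 had one, and of 21 genes of the ventral telencephalon and GABAergic neurons 17 did, with Gad2 at 22.9 and Dlx1 at 20.6. All 18 autism risk genes had a peak, with the kinase Dyrk1a at 46.8 and Pogz at 45.5, and so did all 17 housekeeping genes.

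These 8 lists had more members with a promoter peak than the other genes, of which about 49.5% had one, by Fisher's exact test (two-sided, adjusted over 27 lists). The adjusted p was 2.89e-05 for the pan-neuronal and for the autism risk genes (raw p 3.21e-06 for both), 4.37e-05 for the housekeeping genes, 0.000156 for the cortical projection neurons, 0.000413 for radial glia, 0.000654 for the telencephalic patterning factors, 0.00102 for the synaptic list and 0.00638 for the ventral list. In the lists of replicates 1 and 2 the members with a peak numbered 18 and 18 for the pan-neuronal genes, 13 and 12 for radial glia, 15 and 13 for the synaptic list and 19 and 16 for the ventral list. The members without a peak were Crym among the cortical projection neurons, Grin2a in the synaptic list, and Gsx1, Gsx2, Npy and Sst in the ventral list. Against random genes with promoters of like CpG content the call was lost for the telencephalic patterning factors, whose adjusted p was 0.184 against an expected share of 80.9%, and for the ventral list, whose adjusted p was 1 against an expected 79.8%.

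The intermediate progenitors, the astrocytes and the activity-regulated genes did not pass the threshold. Of 10 intermediate progenitor genes 8 had a peak (adjusted p = 0.0740, Fisher's exact test), with Insm1 at 25.4 and Neurog2 at 14.4, and Neurog1 and Neurod4 had none. Of 10 astrocyte genes 7 had one (adjusted p = 0.227, Fisher's exact test), 8 in replicate 1 and 5 in replicate 2, with Nfix at 29.3 and Gfap at 3.48, while Aqp4, Aldh1l1 and S100b had none. Of 11 activity-regulated genes 8 had one (adjusted p = 0.154, Fisher's exact test), with Dusp1 at 28.6 and Egr1 at 10.3, and Fos, Junb and Nr4a1 had none. In the list of replicate 1 alone 10 of the 11 had one, and the adjusted p was 0.0158. With a window of 2.5 kb it was 0.0160.

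Within the forebrain, 3 lists had few promoter peaks. Of 10 genes of the oligodendrocyte lineage Cnp at 3.30 was the only one with a peak, as it was in the list of each replicate (adjusted p = 0.0277, Fisher's exact test), and the lineage factors Olig1, Olig2 and Nkx2-2, the proteoglycan Cspg4, the receptor Gpr17 and the myelin gene Mbp were among those without. Of 10 genes of Cajal-Retzius cells, the early neurons of the cortical surface, Cxcr4 at 9.42 and Reln at 6.47 had a peak (adjusted p = 0.123, Fisher's exact test), and Barhl2, Calb2, Ebf2, Ebf3, Lhx1 and Lhx5 were among those without. Of 11 diencephalic genes Tcf7l2 at 6.35, Lhx9 at 4.60 and Lef1 at 3.35 had one (adjusted p = 0.227, Fisher's exact test), and Foxb1, Gbx2, Nkx2-4, Olig3, Otp and Pitx2 were among those without. Against random genes of like CpG content the adjusted p was 0.00162 for the Cajal-Retzius list and 0.00225 for the diencephalic list, because 79.6% and 79.9% of such genes had a peak. With a window of 2.5 kb the adjusted p of the oligodendrocyte list was 0.227.

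Markers of other cell types that forebrain tissue can hold had few promoter peaks. None of the 12 microglia genes (adjusted p = 0.00102), the 11 erythroid genes (0.00176) and the 8 choroid plexus genes (0.0111) had one by the replicated list in Fisher's exact test. Of 15 genes of pericytes and meninges Foxc1 at 3.49 had one (adjusted p = 0.00176, same exact test). Of 14 endothelial genes the glucose transporter Slc2a1 at 12.52, the growth factor receptor Kdr at 4.52 and Fli1 at 3.49 had one (adjusted p = 0.0705, same exact test), and the list had 4 members with a peak in replicate 1 and 2 in replicate 2. The choroid plexus call was lost in the list of replicate 1 alone, where Otx2 at 4.02 and Clic6 at 3.36 had a peak (adjusted p = 0.166, same exact test), and with a window of 2.5 kb (0.194), and the microglia call was lost against genes of like CpG content (0.0527, expected share 23.9%). The endothelial list passed the threshold against genes of like CpG content (0.0228) and in the list of replicate 2 alone (0.0344).

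Genes of other tissues and of posterior levels of the nervous system were nearly bare. None of the 39 Hox genes, which pattern the trunk and hindbrain, had a promoter peak in the replicated list or in the list of either replicate (adjusted p = 1.01e-10, raw p 3.74e-12, Fisher's exact test). The same held for the 12 midbrain, hindbrain and spinal cord factors, such as En1 and Atoh1 (adjusted p = 0.00102, same exact test), and for the 14 genes of pluripotency and germ line, such as Pou5f1 and Nanog (0.000413). Of the 12 limb and skeleton genes none had a peak in the replicated list (0.00102), and Runx2 had one of 3.37 in replicate 2. The single members with a peak elsewhere were Myh7, a slow myosin heavy chain, at 16.1 among 21 heart and skeletal muscle genes (adjusted p = 0.000114, same exact test), Krt10, a keratin, at 17.7 among 11 epidermal genes (0.0158), Shh, a signal also secreted in the ventral forebrain, at 6.53 among 12 lung and gut genes (0.00954), and Apoh, an apolipoprotein, at 10.5 among 14 liver genes (0.00310). Of these 4 peaks each was present in the lists of both replicates. The liver call was lost against genes of like CpG content, of which 22.8% had a peak (adjusted p = 0.234, permutation test over random lists).

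**Figure D2:**
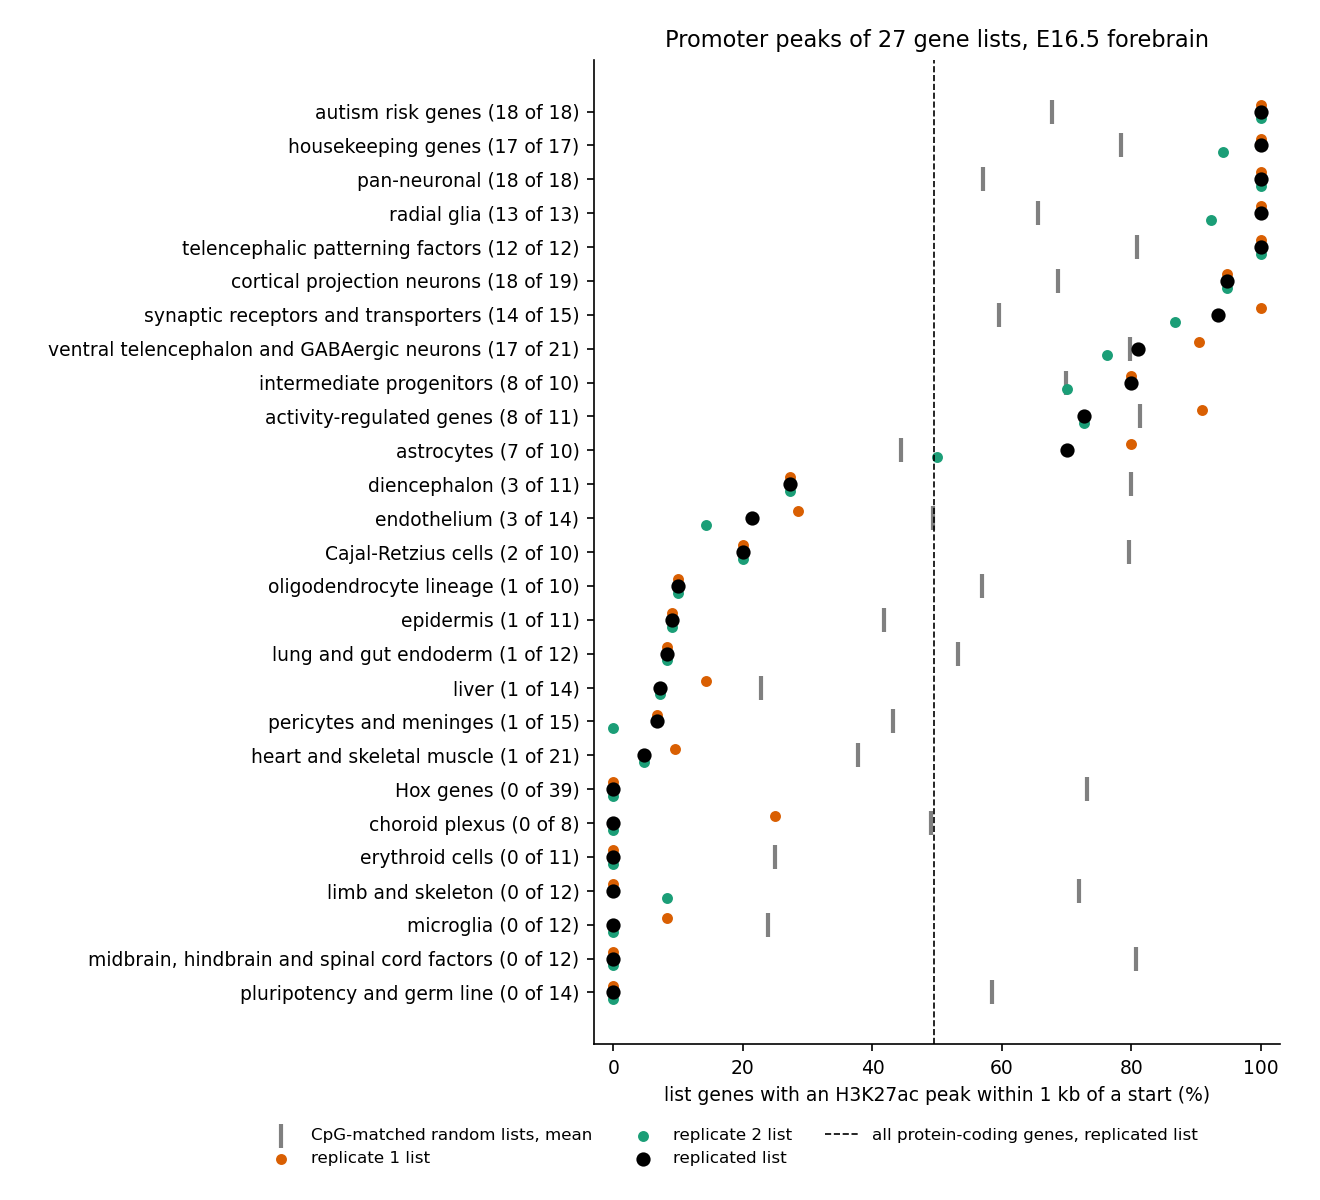
For each of 27 gene lists the share of members with an H3K27ac peak within 1 kb of a start (horizontal axis, percent) is shown for the replicated list (black), replicate 1 (orange) and replicate 2 (green), with the mean of random lists of like promoter CpG content (grey bars) and the share of all protein-coding genes (dashed line, 49.5%). The autism risk, housekeeping, pan-neuronal, radial glia and telencephalic patterning lists lie at 100%, and the Hox, choroid plexus, erythroid, limb, microglia, midbrain to spinal cord, and germ line lists at 0%.

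In all, 21 of the 27 lists passed the threshold of 0.05, 8 with more and 13 with fewer promoter peaks than other genes. Genes were the units of these tests, so the p-values do not measure variation between embryos. Neighbouring genes were counted as independent, and the 39 Hox genes lie only on chromosomes 2, 6, 11 and 15. Their p-value may therefore be too small. An H3K27ac peak in whole tissue does not say which cells carry it.

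Distal peaks were then counted per gene, each peak going to the nearest protein-coding start within 500 kb. Genes of cortical projection neurons had a mean of 30.3 distal peaks, against 5.35 for random genes with a like length of surrounding sequence, a ratio of 5.66. Nfib, a factor of neuronal and glial maturation, had 93, Sox5, a factor of deep-layer neurons, had 73, and Mef2c, a factor of neuronal maturation, had 56. Autism risk genes had a mean of 15.3 against 3.38, a ratio of 4.52, and here the transcription factor Tcf4 had 114, the chromatin remodeller Chd2 had 38 and Foxp1 had 30. A few members carried this mean, since Tcf4 had 114 of the 275 peaks, the mean of the others was 9.47 and the median of the list was 4. Peaks over non-coding genes also count for the nearest protein-coding gene. A stitched region of 22 peaks over Mir9-2 lay nearest to Mef2c, and another, of 20 peaks, over the non-coding gene Gm44734 lay nearest to Chd2. How far such peaks raise the means of these lists was not tested. The ratio was 5.34 in replicate 1 and 6.51 in replicate 2 for the cortical projection neurons, and 4.41 and 4.90 for the autism risk genes. Both lists had an adjusted p of 0.00270 over 27 lists, from the smallest raw p (0.0002) that 10000 random lists can give.

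No other list passed the threshold. The nearest were radial glia, with a mean of 12.6 against 3.78 (adjusted p = 0.0954, permutation test over random lists), intermediate progenitors with 7.80 against 1.89 (0.0972), the ventral telencephalon with 8.33 against 3.63 (0.119) and the telencephalic patterning factors with 13.9 against 5.33 (0.121). In the list of replicate 2 alone the radial glia, intermediate progenitor and ventral lists had an adjusted p of 0.0464. Single genes in these lists had many distal peaks: Sox2 had 47, Id4 44 and Ptprz1 20 among radial glia, Insm1 26, Gadd45g 16 and Btg2 12 among intermediate progenitors, Meis2 55, Isl1 14 and Dlx2 13 in the ventral list, and Nr2f2 42, Nr2f1 38 and Arx 15 among the patterning factors. Astrocyte genes had a mean of 8.10 against 2.93 (0.239), with Sox9 at 42, Nfix at 21 and Fgfr3 at 6. Pan-neuronal genes had 7.94 against 3.92 (0.239), with Rbfox3 at 29 and Ncam1 and Nrxn1 at 21, and synaptic genes had 6.07 against 3.15 (0.307), with Grin2b at 17, Gria2 at 15 and Camk2b at 14.

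The remaining 18 lists had means of 0.103 to 3.73 distal peaks per gene. Activity-regulated genes had 3.73 against 2.03 (adjusted p = 0.434, same permutation test), with Ier2 at 12 and Egr1 and Fos at 6, and housekeeping genes had 1.59 against 0.731 (0.307), with Eef1a1 at 8, Actb at 6 and Psmb2 at 4. Cajal-Retzius genes had 2.5 against 4.25 (0.693), of which Cxcr4 had 17, Lhx5 4 and Calb2 2, diencephalic genes 2.00 against 3.88 (0.606), of which Tcf7l2 had 10, Lef1 6 and Sim1 3, and oligodendrocyte genes 1.6 against 1.34 (0.769), of which Pdgfra had 6, Mbp 3 and Olig2 2. Choroid plexus genes had 2.13 against 3.05 (0.890), with Lmx1a at 8, Kl at 4 and Kcne2 at 2, and endothelial genes 1.86 against 3.36 (0.570), with Slco1c1 at 7, Emcn at 5 and Cdh5 and Slc2a1 at 4. Pericyte and meningeal genes had 0.733 against 2.62 (0.254), with Dcn at 6, Pdgfrb at 3 and Col1a2 at 2, erythroid genes 0.364 against 0.651 (0.890), with Alas2 at 3, Gypa at 1 and Epor at 0, and microglia genes 0.333 against 0.492 (0.921), with Hexb at 2 and Aif1 and C1qb at 1.

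Among other tissues and axial levels, limb and skeleton genes had 1.33 distal peaks per gene against 3.99 (adjusted p = 0.291, same permutation test), with Runx2 at 6, Col2a1 at 3 and Alx4 at 2, and midbrain, hindbrain and spinal cord factors 0.750 against 2.68 (0.254), with Lbx1 at 4, Pax5 at 2 and En1 at 1. Liver genes had 1.36 against 1.18 (0.769), with Apoh at 14, Apob at 4 and Fgg at 1, and muscle genes 0.667 against 0.958 (0.769), with Acta1 and Myog at 3 and Myh7 at 2. Lung and gut genes had 0.750 against 1.78 (0.624), with Scgb1a1 and Shh at 3 and Nkx2-3 at 2, epidermal genes 0.273 against 1.54 (0.307), with Krt1, Krt10 and Tfap2a at 1, germ line genes 0.643 against 1.72 (0.442), with Esrrb at 8, Nanog at 1 and Dazl at 0, and Hox genes 0.103 against 0.285 (0.440), with Hoxa1 at 3, Hoxc4 at 1 and Hoxa10 at 0. When every protein-coding start within 50 kb of a peak was counted, 9 lists passed the threshold, 8 of them higher, with Hox genes the 1 lower list (adjusted p = 0.00135, same permutation test). Neighbouring genes share peaks under that rule but were counted as independent, so the p-value of the Hox genes may be too small.

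**Figure D3:**
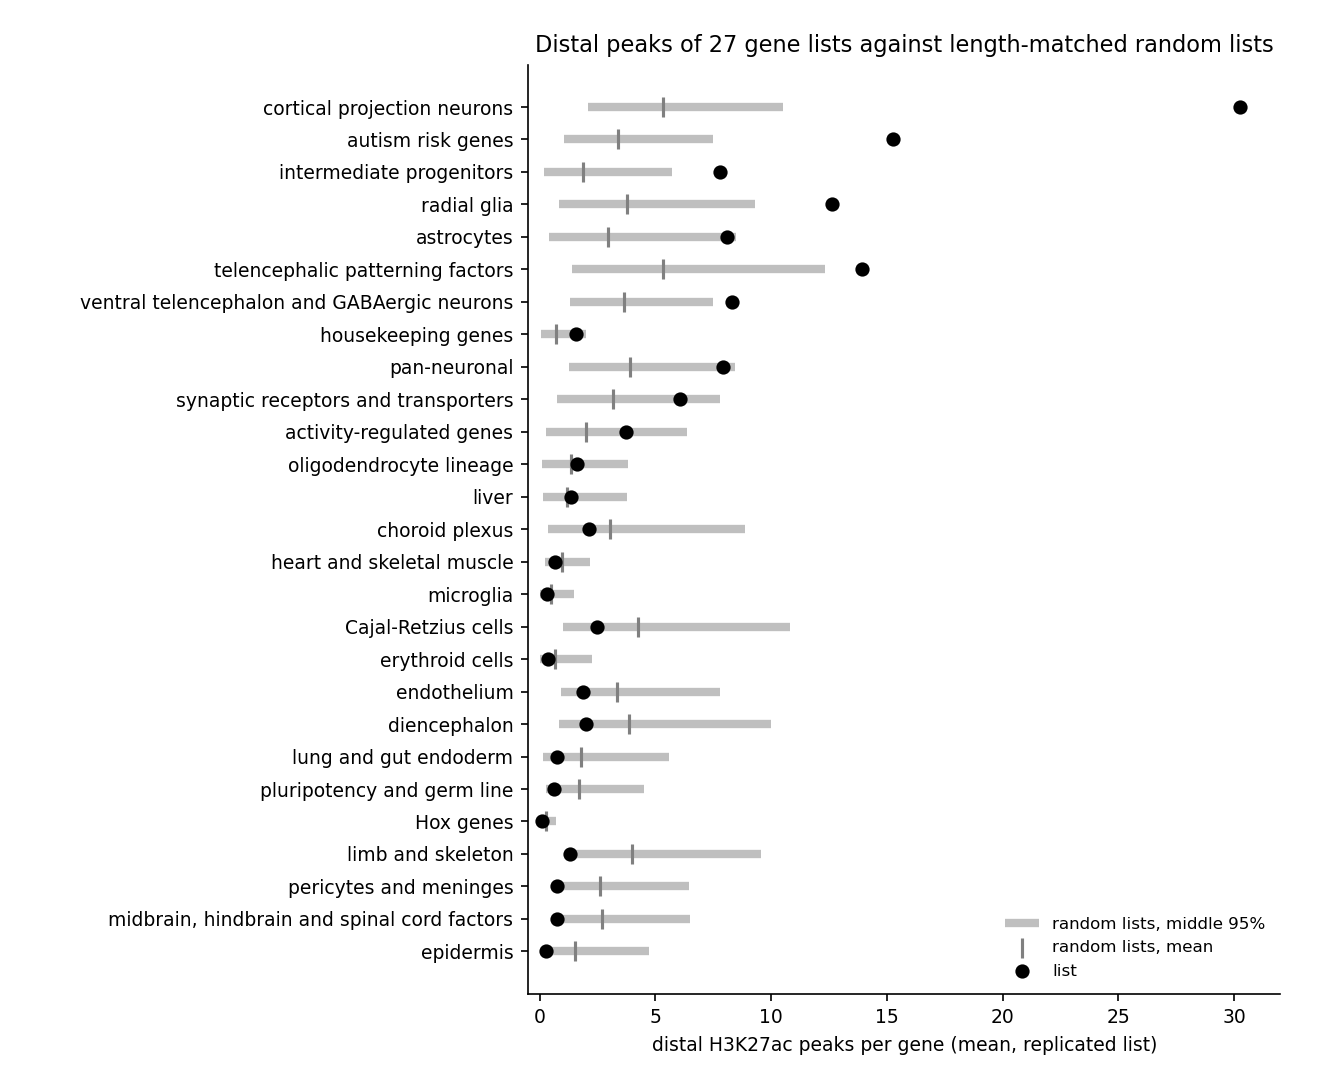
The mean number of distal H3K27ac peaks per gene in the replicated list (horizontal axis, black points) is shown for 27 gene lists, with the mean (grey ticks) and the middle 95% (grey bars) of 10000 random lists matched on the length of sequence nearest to each gene. Cortical projection neurons lie at 30.3 against a random mean of 5.35, and autism risk genes at 15.3 against 3.38.

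Distal peaks within a fixed distance of each other were joined into 15512 stitched regions, which were ranked by signal value times width. The top region (chr3:88197191-88242564) lay between protein-coding genes, 34.8 kb from the start of Rhbg measured from its middle, and held 6 peaks over the microRNA gene Mir9-1 and the long non-coding gene Gm3764. It ranked 1 in both replicates. For all regions, between genes means between protein-coding genes, and non-coding genes can lie there. The second (chr13:83707384-83762380) had 22 peaks between genes, with Mef2c the nearest protein-coding gene and Mir9-2 inside, and the fourth (chr7:79495949-79551005) had 12 peaks, with Polg the nearest gene and Mir9-3 inside. Mir9 is a microRNA of neural progenitors. The third (chr2:30628414-30797360) had 43 peaks, 41 of them between genes, near 1700001O22Rik. Within genes, the regions at Nfix (rank 5), Sdccag8 and Akt3 (7), Ncor2 (8), Gse1 (13), Stra6 and Ccdc33 (15), Nfib (16), Tcf4 (18) and Dscaml1 (20, nearest start that of Cep164) lay mostly in introns. The Tcf4 region (chr18:69496159-69637024) had 60 peaks, the most of the 20. The others lay between genes nearest to Ppara (6), Ubash3b (9), Irf2bpl (10 and 11), Kif13b (12), Chd2 (14), Gm26897 (17) and Foxo6 (19), the last partly in introns.

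The top 5% of the regions held 46.5% of the summed product of signal value and width, against 49.7% in replicate 1 and 45.4% in replicate 2. Of the top 500 regions of each replicate 395 (79.0%) overlapped one of the other's, and circular shifts gave 4.14 on average and at most 11 over 100 shifts.

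**Figure D4:**
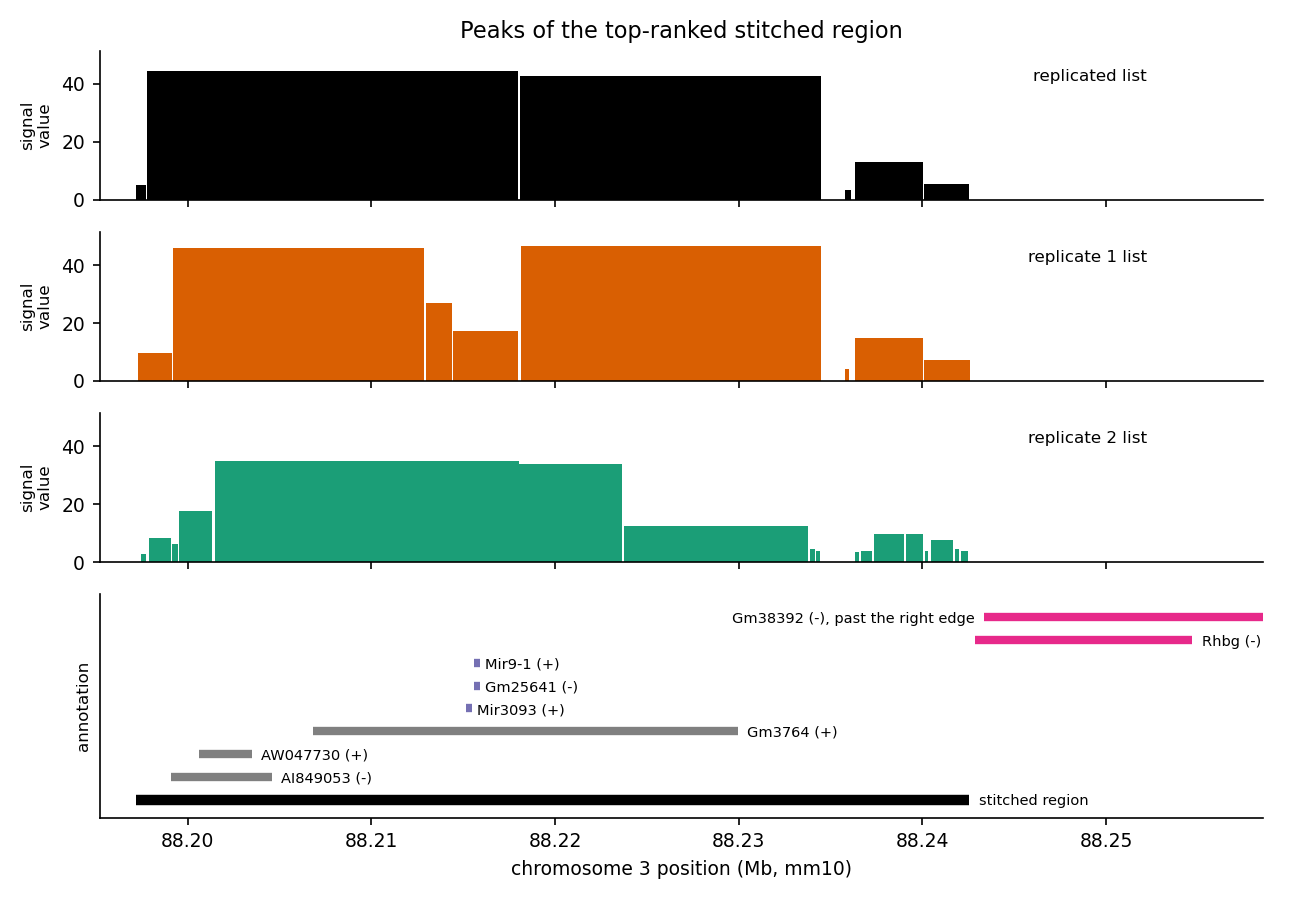
Peaks of the top-ranked stitched region on chromosome 3 (horizontal axis, position in Mb on mm10) are drawn to scale as bars of their signal value (vertical axis) for the replicated list (black), replicate 1 (orange) and replicate 2 (green), above the annotated genes with their strand. The region runs from 88197191 to 88242564 over Mir9-1 and Gm3764, and its highest replicated peak has a signal value of 44.5.

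The last question about sequence was which transcription factor words the 500 bp around distal summits held. Words of neural factors were more frequent than in nearby windows of like GC content. The E-box of NEUROD and NEUROG, factors that drive neuronal differentiation, lay in 17.0% of 35581 windows against 11.9% of as many control windows, a ratio of 1.42, and the ASCL1 E-box in 17.3% against 12.0%, a ratio of 1.44. The homeobox word of DLX and LHX factors had a ratio of 1.44, the POU octamer, bound by the Pou3f factors of cortical neurons, 1.78, and the MEF2 word 2.42. The ratios in the lists of replicates 1 and 2 were 1.367 and 1.444 for the NEUROD E-box, 1.70 and 1.78 for the POU octamer, and 2.17 and 1.94 for MEF2. In windows of 200 bp around the summit the ratios of these words lay nearer 1. They were 1.13 for the NEUROD E-box, 1.31 for the ASCL1 E-box, 1.27 for the homeobox word, 1.32 for POU and 1.82 for MEF2. The word of TBR1 and EOMES was less frequent, in 2.08% against 2.80%, a ratio of 0.744.

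By Fisher's exact test (two-sided, adjusted over 23 words) 21 words passed the threshold. The adjusted p was 7.22e-88 for the ASCL1 E-box, 1.23e-80 for the NEUROD E-box, 4.51e-74 for POU, 3.35e-59 for the homeobox word, 3.72e-25 for MEF2 and 1.63e-09 for the T-box word. Also more frequent were NFI (ratio 3.33), NRF1 (3), EGR (2.5), GRHL (1.69), SP/KLF (1.51), RFX (1.32), CREB (1.31), CTCF (1.27), SRF (1.25), FOXA (1.21) and SOX (1.08), and less frequent were GATA (0.9005), AP-1 (0.886), PU.1 (0.884) and HNF4A (0.761). Some of these ratios rest on few of the 35581 windows: NFI lay in 40 peaks against 12 controls, NRF1 in 42 against 14, EGR in 60 against 24 and GRHL in 59 against 35. By the same exact test HNF1 (ratio 1.63, adjusted p = 0.383) and TEAD (0.952, 0.337) did not pass. In windows of 200 bp the ratio turned to the other side of 1 for CREB (0.944), CTCF (0.635), NRF1 (0.750), SP/KLF (0.848) and GATA (1.07). With repeats left out, a setting chosen after the data were seen, it did so for PU.1 (1.12), GATA (1.01) and the uncalled TEAD (1.02), and with controls of like CpG count for GRHL (0.923) and CREB (0.989). In the turned direction CTCF (adjusted p = 0.000474, same exact test) and SP/KLF (0.0262) passed the threshold in windows of 200 bp and PU.1 (0.0266) without repeats, and the other turned words did not. Leaving out repeats did not rematch the windows on the sequence left to search. Control windows with the PU.1 word fell from 1254 to 836, and peak windows from 1109 to 933. Ratios of that setting may therefore be raised by its construction, and the PU.1 call carries that limit. In windows of 200 bp NFI was found in 5 peaks and 5 controls, and its call was lost. With controls of like CpG count the calls of NRF1 (ratio 1.75, adjusted p = 0.0510, same exact test) and EGR (1.51, 0.0828) were lost. Those of AP-1, CREB, GATA, GRHL, HNF4A, PU.1 and SRF were each lost under at least 1 alternative. Windows were the units of these tests, so the p-values do not measure variation between embryos. Neighbouring windows, some of which may overlap, were counted as independent, so the p-values of the words may be too small.

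**Figure D5:**
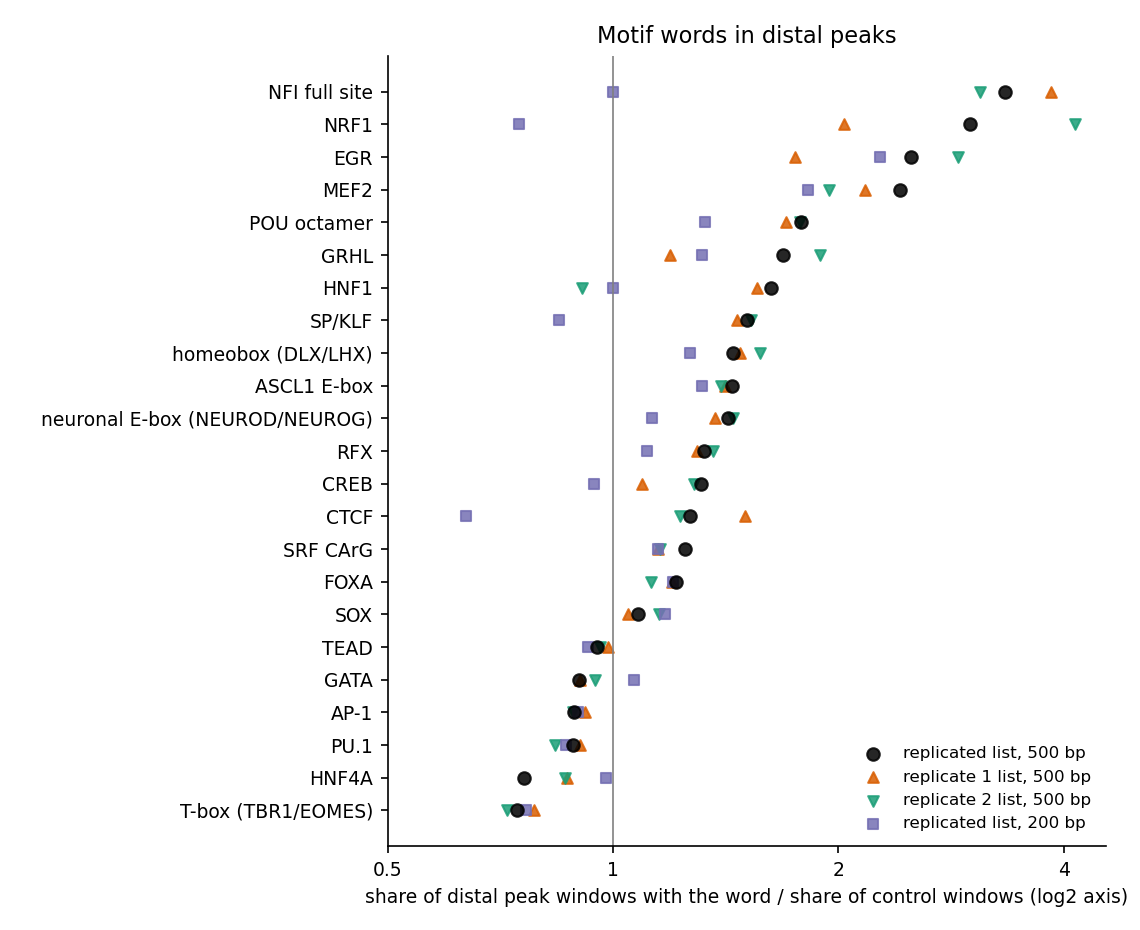
The share of distal peak windows with a word divided by that of control windows (horizontal axis, log2 scale) is shown for 23 words, in black for the replicated list, as orange and green triangles for replicates 1 and 2, and as purple squares for windows of 200 bp. MEF2 lies at 2.42 and the POU octamer at 1.78 in the replicated list, and CTCF lies at 1.27 in windows of 500 bp and at 0.635 in windows of 200 bp.

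Chromosome X carried fewer peaks per length than any autosome in tissue pooled from both sexes. It had 942 replicated peaks, or 5.51 per Mb, against 20.2 per Mb over the autosomes, whose lowest had 15.6 and whose highest had 28.1. The ratio was 0.272 (95% counting interval 0.255 to 0.290), with 0.257 in replicate 1 and 0.274 in replicate 2 (SD 0.0122, n = 2). Neuronal and housekeeping genes on X still had promoter peaks, among them Dcx at 19.2, Hprt at 12.9, Pgk1 at 12.8, the adhesion molecule L1cam at 5.92, the synaptic vesicle proteins Syn1 at 5.77 and Syp at 5.26, and the patterning factor Arx at 5.46. On X 36.1% of genes had a promoter peak, against 50.6% on autosomes.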

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

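These values were looked at only after the data had been seen, and they lie outside the comparisons of the report. Peaks on scaffolds that are not part of the assembled chromosomes were counted because there are no control samples, and each count lay above 3, the limit that a count of 0 allows. No number of such peaks was expected beforehand, so passing that limit shows only that the scaffolds held peaks. Counts on scaffolds do not stand in for control samples. The replicated list held 10 such peaks, the pooled list 11, the list of replicate 1 held 11 and that of replicate 2 held 8, on 5 scaffolds in every list. In each list 1 of them was tall, with a signal value of 48.6 in the replicated and pooled lists, 47.6 in replicate 1 and 39.1 in replicate 2, and the next had 5.42, 5.42, 6.41 and 4.71. No explanation was tested.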

How the results depend on the processing

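Settings with peaks found in both replicates' lists, with starts of all annotated genes and with repeats left out were chosen after the data were seen. Of 27 promoter lists 16 kept their direction and their side of the threshold under all 10 alternatives, among them radial glia, cortical projection neurons, pan-neuronal, autism risk, housekeeping and Hox genes. Of 27 distal lists 16 did under 9 alternatives, among them cortical projection neurons and autism risk genes, and of 23 words 9 did under 9, among them both E-boxes, POU, homeobox, MEF2 and the T-box word. In windows of 200 bp the ratios of these named words lay nearer 1, as with 1.13 for the NEUROD E-box against 1.42 in 500 bp. No called list turned its direction, but 2 promoter and 3 distal lists that were not called did. The 270 alternatives of the promoter lists gave 249 unchanged calls, 7 lost, 12 gained and 2 turned, the 243 of the distal lists 223 unchanged, 10 gained and 10 turned, the 207 of the words 162 unchanged, 32 lost and 13 turned, and the 84 of the other results 49 unchanged and 35 moved. Depth is unknown, so a peak missing from the list of replicate 2 was not shown to be absent there. No paired analysis was possible because the series has a single group.

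For the share of replicate 1's peaks and of replicate 2's peaks found in the other list, an overlap of 1 bp gave 50.3% and 90.1%, 50% of both peaks 35.3% and 58.0%, −log10 q of at least 2 gave 43.1% and 93.8%, of at least 5 gave 45.8% and 97.4%, and the 21167 top peaks of each list 75.1% and 81.6%. The correlation of signal values was 0.808 with 50% of both peaks, 0.778 and 0.792 with −log10 q of at least 2 and 5, and 0.802 with equal numbers. The replicated share of pooled peaks was 99.8% at −log10 q of at least 5. That threshold, the top 50% by signal value and the peaks found in both lists gave promoter shares of 42.5%, 43.6% and 37.3%, genes with a promoter peak of 43.6%, 43.0% and 44.9%, shares of the top stitched regions of 39.9%, 39.8% and 42.1%, and X to autosome ratios of 0.314, 0.335 and 0.293. The stitched share was 43.0% with starts of all annotated genes, and the X ratio was 0.254 in the pooled list. The difference between promoter and distal signal was 3.52 for peaks found in both lists. Leaving out 1 replicate gave 1.79 to 2.59 for that difference, 45.4% to 49.7% for the stitched share, 0.257 to 0.274 for the X ratio and 2 to 5 distal lists past the threshold, the 5 without replicate 1. The stricter lists hold fewer peaks by construction, and for the other changes the cause was not tested.

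Matching on promoter CpG gave an adjusted p of 0.184 for the telencephalic patterning list, 1 for the ventral list, 0.0527 for microglia and 0.234 for liver, whose calls were lost, and of 0.00162 for Cajal-Retzius cells, 0.00225 for the diencephalon and 0.0228 for endothelium, whose calls were gained. A window of 2.5 kb gave 0.227 for oligodendrocytes, 0.0160 for activity-regulated genes, 0.0416 for endothelium and 0.194 for choroid plexus. Endothelium also passed at −log10 q of at least 5 (0.00862), in the top 50% by signal value (0.0390), in the pooled list (0.0403), in peaks found in both lists (0.0352) and with the most upstream start (0.0208). Leaving out 1 replicate gave 0.0158 to 0.142 for activity-regulated genes (lowest without replicate 2), 0.0344 to 0.121 for endothelium (lowest without replicate 1) and 0.0134 to 0.166 for choroid plexus (highest without replicate 2). For distal peaks, every start within 50 kb gave 9 lists past the threshold, with 0.00135 for the telencephalic patterning and, lower, for the Hox genes, 0.00864 for intermediate progenitors, 0.0177 for the ventral and pan-neuronal lists, 0.0196 for astrocytes and 0.0402 for activity-regulated genes. Leaving out 1 replicate gave 0.0464 to 0.0972 for radial glia, 0.0464 to 0.112 for intermediate progenitors and 0.0464 to 0.109 for the ventral list, each lowest without replicate 1. Over all alternatives the adjusted p of promoter peaks ran from 0.000214 to 0.184 for telencephalic patterning, 0.000603 to 1 for the ventral list, 0.00162 to 0.227 for Cajal-Retzius cells, 0.00347 to 0.227 for oligodendrocytes, 0.00225 to 0.254 for the diencephalon, 0.0158 to 0.765 for activity-regulated genes, 0.000556 to 0.0527 for microglia, 0.00862 to 0.121 for endothelium, 0.00162 to 0.194 for choroid plexus and 0.00317 to 0.234 for liver. That of distal peaks ran from 0.00135 to 0.205 for telencephalic patterning, 0.0464 to 0.124 for radial glia, 0.00864 to 0.116 for intermediate progenitors, 0.0177 to 0.195 for the ventral and to 0.440 for the pan-neuronal list, 0.0196 to 0.402 for astrocytes, 0.0402 to 0.570 for activity-regulated genes and 0.00135 to 0.550 for Hox genes. Lists that turned stayed short of the threshold. For promoter peaks these were astrocytes at −log10 q of at least 5 (40.0% against 43.6%, adjusted p = 1) and activity-regulated genes matched on promoter CpG (72.7% against 81.3%, 0.719, permutation test). For distal peaks they were oligodendrocytes and liver, from higher to lower, at −log10 q of at least 5 (0.979 for both), in the top 50% by signal value (0.882 and 0.610) and with every start within 50 kb (1 and 0.525), oligodendrocytes also in peaks found in both lists (0.933) and without replicate 1 (0.780 to 0.853 on leaving out 1 replicate), liver also at a limit of 100 kb (0.711), and muscle, from lower to higher, with every start within 50 kb (0.505).

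Ratios of words turned to the other side of 1 in windows of 200 bp for CREB (0.944), CTCF (0.635), NRF1 (0.750), SP/KLF (0.848) and GATA (1.07), with controls matched on GC and CpG for CREB (0.989) and GRHL (0.923), without repeats for GATA (1.01), PU.1 (1.12) and TEAD (1.02), in the pooled list for TEAD (1.02), and at −log10 q of at least 5 (0.778) and without replicate 1 (0.909, with 1.56 without replicate 2) for HNF1. In the turned direction only CTCF, SP/KLF and PU.1 passed the threshold, and HNF1 and TEAD were not called in any setting. PU.1 did so only without repeats, where windows were not matched on the sequence left to search. Calls were lost for NFI in windows of 200 bp (ratio 1) and with controls matched on GC and CpG for NRF1 (1.75) and EGR (1.51). The cause was not tested for these lists and words.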

Other observations

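The families, the microRNA lists, the widest peaks and the genes with most distal peaks in this part were chosen after the data were seen, as were the tests of depth, of the threshold and of kept and full lists for replicate 1's list, of gene surroundings on X, and of chance and of long non-coding starts for the microRNA genes. Gene families differed in how many members carried a promoter peak. All 18 histone lysine demethylases had one, as did 73 of 76 ribosomal protein genes (96.1%), 56 of 66 replication histone genes (84.8%) and 265 of 365 Zfp zinc finger genes (72.6%), against 69.9%, 76.9%, 76.0% and 51.4% for genes of like promoter CpG content. Of 57 clustered protocadherins, adhesion molecules that give neurons their identity, 7 had one (12.3%) against 45.7% for genes of like CpG content (adjusted p = 7.01e-09, Fisher's exact test against all other genes, over 16 families). Members of a cluster were counted as independent, so that p-value may be too small. Of 1092 olfactory receptors 2 had one and of 42 defensins 0, against 2.46% and 5.96% for genes of like CpG content. Of 19 Sox factors 13 had one (adjusted p = 0.120, same exact test) and of 43 Fox factors 19 (44.2%, adjusted p = 0.543), and neither family passed the threshold. Genes of like CpG content had 74.1% and 72.7%. For none of the families was the difference from genes of like CpG content tested.

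The widest peak of the replicated list, of 20217 bp, lay over Mir9-1 (chr3:88197774-88217990). The widest peak overlapping it had 13684 bp in replicate 1 and 16541 bp in replicate 2. Those ranked 2 and 5 (16383 and 12205 bp) lay at no protein-coding start and held no microRNA gene, those ranked 3 and 6 lay over Mir9-3 (14605 bp) and Mir124a-1 (11693 bp), and those ranked 4 and 7 lay at Tnrc18 (14191 bp) and Islr2 (11463 bp). Widths were not always alike in the replicates' lists, as at Tnrc18, with 13742 bp in replicate 1 and 6512 bp in replicate 2. Foxg1 followed with 10957 bp (chr12:49375391-49386347), where the widest peak of replicate 1 had 6010 bp, and the 20 widest also held peaks at Meis2, Bcl11a, Mn1, Fezf2, Nfix, Efnb2 and Bcl11b. The genes with most distal peaks were the RNA-binding Celf2 with 124, Tcf4 with 114, Auts2 with 110, Tenm4 with 94, Nfib with 93 and the neuronal repressor Myt1l with 88. These counts were not matched on the length of sequence nearest to the gene, which was 1359 kb for Celf2. Per 100 kb of that sequence these genes had, in the same order, 9.12, 12.9, 6.64, 7.88, 12.0 and 11.3 peaks. Gse1, ranked 7 by count, had 22.2. Of 15 microRNA genes known from brain 12 lay in a stitched region, 10 of them in the top 500, against 0 of 15 known from other tissues. The brain list was drawn up after several of its members had been seen in the top regions, so these counts carry no test. Mir124a-1, Mir124a-2 and Mir124a-3, copies of a microRNA of neurons, lay in regions ranked 12, 31 and 56.

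The list of replicate 1 was longer than that of replicate 2, by a ratio of 1.64. With the same cut in both lists the ratio was 2.02 (59053 against 29287 peaks) at −log10 q of at least 2 and 2.04 at 5. That argues against a looser caller's threshold for replicate 1 only if q-values mean the same in both lists. Replicate 1's list, unlike replicate 2's, drew on 1 further file of unstated role, so this was not shown. Whether that file lengthened the list was not tested. Other tissue carried along in replicate 1 and a difference in depth cannot be told apart, since depth is unknown, replicate 1 had the lower p-value in 91.8% of 31799 overlapping pairs, and the 99.94% of the highest decile of its peaks (n = 6956) that had a partner in replicate 2's list would be so with weak peaks of either origin. With 42334 top peaks from each, the largest difference in any list of other cells or tissues was 1 member, but only 38.2% of replicate 1's 36538 peaks without a partner were kept, and in the full lists members were gained by lists of other cells (endothelium 4 against 2, choroid plexus 2 against 0) and of forebrain (ventral 19 against 16, astrocytes 8 against 5) alike. No biological explanation was tested, as both replicates belong to 1 group.

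Peaks were sparse on X, where the density outside repeats was still 0.346 of that on autosomes, which argues against more repeats on X as the whole cause. X genes had 0.174 of the distal peaks of autosomal genes with like surroundings (0.477 against 2.74, range 2.20 to 3.38 over 1000 draws), which argues against fewer genes or shorter surroundings for the distal peaks. CpG-poor promoters on X may account for its fewer promoter peaks per gene, since the share of X genes with one was 0.946 of that of autosomal genes of like CpG content (36.1% against 38.1%, range 34.3 to 42.4). A lower signal per X copy cannot be told apart from none, because only peaks past the caller's threshold have a signal value; among these the median was 0.949 of that of matched autosomal peaks. Silencing of 1 X in female embryos and the single X of males remain open as untested explanations, and the scarcity of distal peaks was left without a tested account.

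MicroRNA genes lay in 8 of the top 20 stitched regions, and in 7 for each replicate's list. Chance placement was argued against, since 0 of 100 circular shifts placed as many there (mean 0.880, at most 5). Of 492 lower regions at least as long as the shortest top region, 25.03 kb, 26 (5.28%) held one (p = 1.17e-05, Fisher's exact test). Long regions in gene-rich sequence were left open, because gene density was not measured and lengths were matched only at that lower limit. The pattern was first seen in these same top regions. Whether it comes from starts of long non-coding genes, counted as distal here, was also left open. Only 3 of the top 20 regions held a microRNA gene once peaks at such starts were removed. But all 8 holding regions had a peak at one, as did 8 of the other 12, so the removal itself took peaks from most of them. No biological explanation was tested; a candidate reading is that the regions mark promoters of microRNA host transcripts, such as Mir9-3hg, and the lists hold no transcript to test it.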
